A study of Mus musculus with 12 samples.

How the data were processed

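Total RNA from the livers of 12 male C57BL/6 mice aged 8 to 10 weeks was measured, per the labels, on one-colour arrays, 1 mouse per array. Per the labels' protocols, all mice were adrenalectomized, treated mice received dexamethasone at 1 mg/kg into the peritoneum, livers were taken after 6 hours, and 500 ng of RNA was labelled with Cy3. No vehicle injection of the untreated mice is described. The series design states 3 mice in each of the 4 groups, so replicates are separate animals. Groups were taken from the sample titles.

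The values used were array intensities. Per the file headers, the authors extracted them with Agilent Feature Extraction 9.5.3.1 (9.5 per the submitters' processing notes), on an array design drawn on the mm7 build of the mouse genome. Each deposited array file holds 45018 spots, of which 1639 are controls. The processed signal in these files is an intensity on a linear scale from which the software had already removed background, per the file headers. The deposited series table also holds intensity values; each of its 12 columns equalled the processed signal of its array (ratio 1), so its scale is linear, unscaled between arrays and not centred. Its column medians ran from 53.7 to 112. The labels state no further normalization.

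Signals were scaled here as the log2 processed signal minus the 75th percentile of its array, over non-control spots. Spots marked as outliers by the software were left out, saturated spots were kept, and spots of one probe were averaged. Of 41174 probes, 22951 were named through their accession in the reference table of mouse genes, 9768 by symbol or synonym, 1258 kept the name in the file and 7197 had no gene name. The probe with the highest mean over the 12 arrays stood for its gene. Among called named genes with several probes, the other probes never had the opposite sign in any comparison. The size of the log2 change could differ between probes. With dexamethasone in wild-type liver it was 3.06 and 5.45 for Mt1 and -1.09 and -0.24 for Fam219b, but 5.13 and 5.45 for Gadd45b. In HESKOL liver it was -3.55 and -8.18 for Car3. Changes given below are those of the probe that stood for the gene. Genes were tested where the probe was well above background on all 3 arrays of at least 1 group, which left 18728 of 27822 genes. Where a gene was not well above background on any array of a group, the change is given as a lower bound ("at least"), from the mean of the brighter group and, in the dimmer group, the higher of the probe's signal and the lowest signal well above background on each array. Coordinates are those of the mm7 design, and no genome of that build was used here.

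Group means were fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 8 residual and 3.12 prior degrees of freedom. The 5 contrasts were dexamethasone in wild-type liver, dexamethasone in HESKOL liver, HESKOL against wild-type without and with treatment, and the difference between the dexamethasone effects. P-values were adjusted within a contrast by the Benjamini-Hochberg method, with a threshold of 0.05. Hes1 was also compared by an exact two-sided permutation test of 3 against 3 arrays. Before the data were examined, 31 gene lists were fixed, 21 of pathways and 10 of cell type markers, of which all had at least 5 tested members. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, and adjusted over the 31 lists of a contrast. Over the 5 contrasts 66 camera tests passed, 2 passed with an estimated correlation and 14 passed with fry, which asks only whether a list's genes move one way on balance.

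Also before the data were examined, the genes named in the text were set by a rule: in each comparison the 10 largest increases and 10 largest decreases past the threshold among genes whose groups did not overlap, or the 5 smallest p where none passed, leaving out unnamed gene models. Hes1, 15 known glucocorticoid or liver genes and up to 4 members of each list were added; Zbtb16, among them, had no probe. Pcdh19 and Rspo4, and Lpl for dexamethasone in HESKOL liver, lie outside the rule and were chosen after their values were seen. Some genes that the rule named are not reported here.

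The alternatives were quantile normalization, median scaling, normexp background correction, the deposited table, no filter, other ways to combine probes, slide as a fixed or random block, the replicate number as a block, an intensity trend with robust estimation, fits on the groups compared alone, a stricter threshold, a minimum log2 change of 1, and each array left out in turn. Array weights, array brightness as a covariate and the joint removal of 2 treated arrays were chosen after seeing the data. Median scaling moved the median change of all genes by dexamethasone in HESKOL liver from -0.003 to 0.10, and the unscaled deposited values moved medians to between -0.35 and 0.25 over the 5 contrasts. Fits were tested on simulated data with 200 changed genes among 18728. For dexamethasone in wild-type liver, 66% of genes changed by a log2 value of 2 were recovered and 10% of those changed by 1; for the difference in response these shares were 42% and 12%. With no change simulated, the 5 contrasts made 0 or 1 calls. With the 200 changed genes, false calls made up 3.73% (dexamethasone in wild-type liver) to 8.03% (between treated genotypes) of the calls. The simulated errors were independent between genes and arrays. Deviations of the real arrays from their group means correlated at -0.71 to 0.71 between arrays of different groups, so these rates may not carry over to the real arrays. Figures were drawn with Python 3.11.15.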

Results

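Gene expression was measured in mouse liver on 12 one-colour arrays, one per mouse. Wild-type mice and mice labelled HESKOL were left untreated or received dexamethasone, a synthetic glucocorticoid, with 3 mice in each of the 4 groups. The labels do not spell out HESKOL, and the study's title names Hes1, a transcriptional repressor downstream of Notch, together with liver glucocorticoid signaling. All mice were adrenalectomized, which removes their own source of glucocorticoids, so the hormone signal came from the injection of 1 mg/kg given 6 hours before the liver was taken. Between 62.2% and 72.3% of the probes were well above background on each array, and array brightness, as the 75th percentile of signal, ran from 897 to 1614 units. After filtering, 18728 of 27822 genes were tested. The number of arrays, 3 per group, limits the precision. Values are log2 signals relative to the 75th percentile of their own array, and differences are log2 changes with their standard error (SE).

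The 12 arrays lay on 3 slides of 4, and each slide was scanned in 1 run. Slide 1 held the 3 untreated wild-type livers and HESKOL untreated replicate 1. Slide 2 held HESKOL untreated replicates 2 and 3 with wild-type dexamethasone replicates 1 and 2, and slide 3 held wild-type dexamethasone replicate 3 with the 3 HESKOL dexamethasone livers. Each genotype comparison therefore has 1 slide with both groups on it, whereas no slide holds treated and untreated livers of the same genotype. With slide as a block, a genotype difference equals the difference within the shared slide, and a dexamethasone effect is the sum of differences within 2 slides that pass through the other genotype. Each comparison below gives these blocked values. In wild-type liver the blocked dexamethasone effect rests on treated replicates 1 and 2, which lie on slide 2. Treated replicate 3, on slide 3, does not enter it. A blocked shift in wild-type liver can therefore come from this change of arrays as well as from the slides. In the plot of principal components, the first component (38.5% of variance) placed 5 of the 6 treated livers between 29.6 and 86.4 and the untreated livers between -74.2 and -7.98, and wild-type dexamethasone replicate 1 lay among the untreated ones, at -35.8. That array also deviated most from the mean of the other 2 arrays of its group, by 0.994 log2 units (root mean square), against 0.463 to 0.799 for the other 11.

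**Figure D1:**
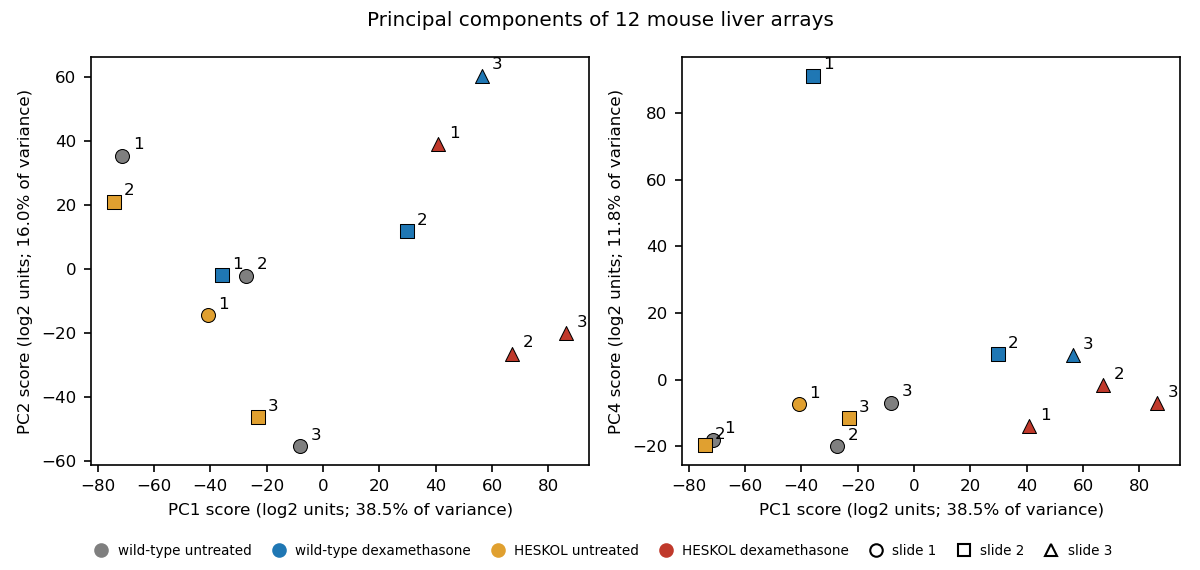
Principal component scores of the 12 arrays over 18711 genes without missing values (left, components 1 and 2; right, components 1 and 4; axes in log2 units). Colours mark the 4 groups, shapes the 3 slides and numbers the replicates; wild-type dexamethasone replicate 1 lies at 91.2 on component 4 (11.8% of variance), and the other 11 arrays lie between -20.02 and 7.65.

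Hes1 signal was lower in HESKOL than in wild-type liver. Untreated HESKOL livers averaged -2.65 ± 0.38 (SD, n = 3) and untreated wild-type livers -1.53 ± 0.34 (SD, n = 3), which puts HESKOL at 46.1% of the wild-type signal. After dexamethasone the averages were -3.32 ± 0.47 (SD, n = 3) in HESKOL and -2.22 ± 0.93 (SD, n = 3) in wild-type liver, or 46.7%. All 3 HESKOL livers lay below all 3 wild-type livers in both comparisons, with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow. The limma adjusted p was 0.9999 without and 0.249 with treatment, so the difference did not pass the transcriptome-wide threshold. Within slide 1 the difference was -0.93 (SE 0.58) and within slide 3 it was -0.40 (SE 0.58). The gene has 1 probe, on chromosome 16 from 29738743 to 29739038 of the mouse assembly mm7 given in the file headers. The labels do not say which part of the gene was altered, so this probe may lie outside it and is a limited check of the genotype labels. Dexamethasone changed Hes1 by -0.69 (SE 0.43, adjusted p = 0.577) in wild-type and -0.67 (SE 0.43, adjusted p = 0.369) in HESKOL liver, neither past the threshold. The change in wild-type liver was -1.21 (adjusted p = 0.0618) and the difference between treated genotypes -0.57 when wild-type dexamethasone replicate 1 was left out.

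**Figure D2:**
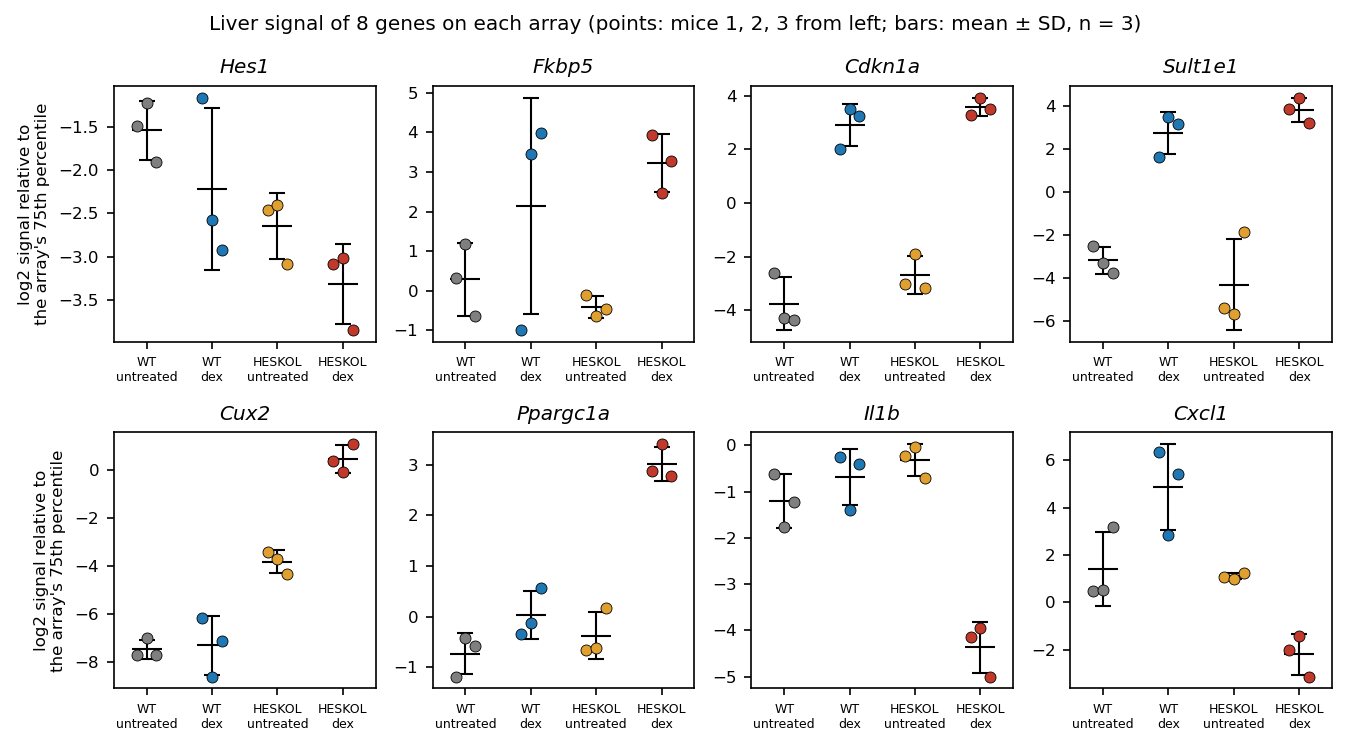
Signal of 8 genes on each of the 12 arrays (y axis, log2 signal relative to the array's 75th percentile; x axis, the 4 groups). Points are single mice, replicates 1 to 3 from left to right, and bars are the mean ± SD (n = 3); Cux2 in HESKOL dexamethasone liver and Cxcl1 in wild-type dexamethasone liver are the highest groups of their panels.

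The first question was which liver genes respond to dexamethasone in wild-type mice. The largest increases were in Fam107a (log2 change 8.79, SE 1.05, 444-fold, with 1 of 3 untreated arrays above background), in Cdkn1a, a cyclin-dependent kinase inhibitor (6.66, SE 0.54, 101-fold), in the estrogen sulfotransferase gene Sult1e1 (5.93, SE 0.87, 61.0-fold), in Gadd45b (5.45, SE 0.51, 43.7-fold) and in Igfbp1, a secreted binding protein of insulin-like growth factors (5.45, SE 0.79, 43.7-fold). Gdf15 (30.9-fold), Cldn14 and Rasd1 (12.1-fold each), Retreg1 (8.72-fold), the metallothionein gene Mt1 (8.36-fold) and the phosphatase gene Dusp1 (7.14-fold) also rose. Hacl1, which acts in peroxisomal alpha-oxidation, fell 4.75-fold, Wnt5b 2.75-fold, Nmrk1 2.68-fold and Fam219b 2.13-fold. Cd180 fell at least 3.62-fold and Rpl3l at least 1.18-fold, since neither was well above background in treated liver. In all of these genes the 3 treated livers lay on one side of the 3 untreated ones, which the rule for naming the largest changes required. The log2 change was 10.46 for Fam107a, 4.84 for Gadd45b and 4.14 for Gdf15 without wild-type dexamethasone replicate 1.

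In total 30 genes rose and 6 fell in wild-type liver (limma, adjusted p under 0.05), with 2203 genes at an unadjusted p under 0.05 against 936 expected by chance. The groups of arrays did not overlap in 12.1% of all tested genes, where chance gives 10%. Without wild-type dexamethasone replicate 1 the count was 1110 (472 up, 638 down), and all 36 genes were among them with the same sign. It was 101 without replicate 2 and 11 without replicate 3 of that group, 13, 12 and 15 without wild-type untreated replicates 1, 2 and 3, 20, 23 and 22 without HESKOL untreated replicates 1, 2 and 3, and 22 without HESKOL dexamethasone replicate 1. The split of 30 and 6 was 17 up and 25 down on the unscaled deposited values, where the median change of all genes was -0.35, and 32 and 13 after normexp correction and quantile normalization. With slide as a block no gene passed (610 at an unadjusted p under 0.05), the 36 genes kept their signs, and their median SE rose from 0.34 to 0.61.

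Among the gene lists fixed beforehand, the glucocorticoid receptor targets moved most clearly in wild-type liver. All 23 measured members had a positive change (median 1.73), 4 of them passed over all genes (Cdkn1a, Igfbp1, Mt1 and Dusp1) and 15 passed when adjusted over the list alone. The list's camera test gave an adjusted p of 2.5e-21, and it was the 1 list of 31 to hold in this comparison with an estimated correlation (adjusted p = 0.0246 with an estimated correlation). The median was 1.56 and 10 members passed over all genes without wild-type dexamethasone replicate 1, while the test with an estimated correlation then gave adjusted p = 0.118. Its median under the slide block was 0.86. Members that missed the threshold over all genes included Tat, tyrosine aminotransferase (1.49, SE 0.29, adjusted p = 0.0935), the kinase gene Sgk1 (1.96, SE 0.40, adjusted p = 0.107), Fkbp5, a co-chaperone of the receptor (1.85, SE 1.05, adjusted p = 0.531), Per1 (0.99, SE 0.42, adjusted p = 0.388) and Tsc22d3 (0.54, SE 0.60, adjusted p = 0.786). In wild-type dexamethasone replicate 1, the signals of Fkbp5 and Tsc22d3 (2.40) lay below the highest untreated array (1.19 and 3.75). Without that array Fkbp5 changed by 3.42 (adjusted p = 0.00869) and Tsc22d3 by 1.38 (adjusted p = 0.0629).

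Other lists had positive medians in treated wild-type liver. The 21 immediate early genes had a median change of 2.19 (2.38 with slide as a block), with 2 genes up over all genes, Dusp1 and Gadd45b, and 12 up adjusted over the list alone; the camera call was lost at adjusted p = 0.276 with an estimated correlation. This list stood at 3.79 in wild-type dexamethasone replicate 1 and at 0.64 and 1.27 in the other 2 treated livers, and without replicate 1 its median was 0.76. All 21 genes of the unfolded protein response had positive changes (median 0.82, or 0.77 with slide as a block), none past the threshold over all genes and 11 adjusted over the list alone (adjusted p = 0.241 with an estimated correlation; Hspa5 1.55, SE 0.37). Its median was 1.33, with 9 of 21 members past the threshold over all genes, without wild-type dexamethasone replicate 1. Camera with its preset correlation also called heat shock proteins (median 0.62, adjusted p = 0.276 with an estimated correlation), acute phase proteins (median 0.43, adjusted p = 0.333 with an estimated correlation), amino acid catabolism (median 0.24), hepatocyte markers (median 0.24) and NF-kB and cytokine genes (median 0.52), the last 3 at adjusted p = 0.739 with an estimated correlation, and adipocyte markers (median 1.02, adjusted p = 0.276 with an estimated correlation). The calls of the NF-kB list (median 0.08), hepatocyte markers (0.16) and adipocyte markers (0.32) were lost without wild-type dexamethasone replicate 1. The median of amino acid catabolism was then 0.40. Under the slide block the medians were 0.64 for heat shock, 0.16 for acute phase, 0.43 for amino acid, 0.31 for hepatocyte, 0.58 for NF-kB and 0.74 for adipocyte lists, and the acute phase call was lost (adjusted p = 0.397). These blocked medians rest on treated replicates 1 and 2, so they are no check apart from replicate 1. The NF-kB list stood at 1.25, -0.46 and 0.70 in treated replicates 1, 2 and 3. The median of the hepatocyte list was negative after quantile normalization (-0.012) and on the unscaled deposited values (-0.091), and that of the amino acid list on the latter (-0.089). The receptor gene itself, Nr3c1 (-0.14, SE 0.18), the metallothionein gene Mt2 (1.73, SE 0.46), the acute phase gene Lcn2 (3.11, SE 1.08) and the bile acid gene Cyp7a1 (-0.22, SE 0.65) did not pass.

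Lists with negative medians in treated wild-type liver were interferon response (-0.62), cholesterol biosynthesis (-0.73, 24 genes), cell cycle (-0.88) and lymphocyte markers (-0.65), each called by camera and each at adjusted p = 0.739 with an estimated correlation. No member of these lists passed over all genes or adjusted over the list alone. Under the slide block the medians were -0.24, -0.32, -1.44 and 0.13, so that of the lymphocyte markers changed sign. The calls of interferon response (adjusted p = 0.816), cholesterol biosynthesis (adjusted p = 0.211) and lymphocyte markers (adjusted p = 0.830) were lost under that block. The blocked values rest on wild-type dexamethasone replicates 1 and 2. The slides and replicate 1 therefore cannot be told apart as the source of these losses. Without wild-type untreated replicate 1 the median of the cell cycle list was 0.21. Without wild-type dexamethasone replicate 1 the cholesterol list stood at -1.33 with 12 of 24 members down over all genes, the interferon list at -1.07 with 7 of 23 down and lymphocyte markers at -1.15.

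The second question was which genes respond to dexamethasone in HESKOL liver. Fam107a rose at least 923-fold, Sult1e1 280-fold (log2 change 8.13, SE 0.87), Cdkn1a 76.7-fold (6.26, SE 0.54) and Gadd45b 47.4-fold (5.57, SE 0.51). Cidec, a lipid droplet protein, rose 51.3-fold, thyroglobulin (Tg) 88.7-fold, Serpina5 46.0-fold, Stmn2 at least 46.7-fold, Lancl3 at least 16.7-fold and Itga2 at least 16.1-fold. The largest decreases were in Rnf186 (81.1-fold; log2 change -6.34, SE 0.77), the water channel gene Aqp8 (32.0-fold), Dclk3 (29.9-fold), Acod1, which makes itaconate in activated macrophages (26.7-fold), Nrep (19.6-fold), Kcnj10 (17.8-fold), Gadd45a (17.0-fold) and the lipogenic transcription factor gene Srebf1 (16.6-fold), and Hao2 fell at least 6.11-fold. Tg and Serpina5 were above background on 1 of 3 untreated arrays each, and Dclk3 on 2 and Acod1 on 1 of 3 treated arrays. For each of these genes all 3 treated livers lay on one side of all 3 untreated ones, again a condition of the naming rule. Of the genes named in wild-type liver, Gdf15 (0.13), Hacl1 (0.41), Wnt5b (-0.05), Rpl3l and Fam219b (-0.41) did not pass in HESKOL liver. None of them was called in the test of the difference between the responses, so a response particular to wild-type liver was not shown for them.

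In all, 682 genes rose and 791 fell in HESKOL liver (limma, adjusted p under 0.05), with 4613 at an unadjusted p under 0.05, and the groups did not overlap in 34.3% of tested genes, where chance gives 10%. The split of 682 against 791 moved with the scaling: on the medians of the arrays it was 727 up and 623 down, where the median change of all genes was 0.10, compared with -0.003 on the 75th percentile. With slide as a block no gene passed (1201 at an unadjusted p under 0.05), 1454 of the 1473 genes kept their sign, and their median change in that sign was 1.01 with a median SE of 0.58, compared with 1.54 and 0.33 without it. The count was 2801 without wild-type dexamethasone replicate 1. Without a slide block, that array enters this comparison only through the shared estimate of spread and the set of tested genes (18798 without it). Under the slide block it enters the HESKOL values directly, as 1 of the 2 treated wild-type livers of slide 2. Blocked shifts can therefore come from that array as well as from the slides. The cholesterol list stood at 0.51 in it and -1.19 in replicate 2, and lymphocyte markers at 0.37 and -0.85. The count was 364, 368 and 974 without HESKOL untreated replicates 1, 2 and 3, and 791, 387 and 570 without HESKOL dexamethasone replicates 1, 2 and 3.

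Glucocorticoid receptor targets rose in HESKOL liver, with 15 of 23 past the threshold over all genes and 21 higher and 1 lower adjusted over the list alone (median 2.28, or 1.44 with slide as a block; adjusted p = 0.0657 with an estimated correlation). They included Ddit4 (5.24, SE 0.68), Lpin1 (4.69, SE 0.66), Igfbp1 (3.49, SE 0.79), the pyruvate dehydrogenase kinase gene Pdk4 (2.46, SE 0.56), Per1 (2.32, SE 0.42), Sgk1 (2.03, SE 0.40), Dusp1 (1.96, SE 0.26) and Tat (1.40, SE 0.29). Fkbp5 (3.63, SE 1.05, adjusted p = 0.0577) and Tsc22d3 (1.88, SE 0.60, adjusted p = 0.0813) missed the threshold. Enzymes of amino acid catabolism and the urea cycle also rose, 10 of 21 over all genes and 13 adjusted over the list alone (median 1.08, or 1.23 with slide as a block; adjusted p = 0.467 with an estimated correlation). Examples were Got1 (2.72), the ornithine transporter gene Slc25a15 (2.49), Tdo2 (2.28) and Aass (2.05).

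Glucose and lipid genes went in both directions in treated HESKOL liver. In the list of gluconeogenesis and glucose output, Ppargc1a, a coactivator of gluconeogenic genes (3.39, SE 0.33), Got1 and Gpt2 (1.71) rose, whereas the pyruvate kinase gene Pklr (-1.59), which acts in glycolysis, fell (median 0.91, or 0.94 with slide as a block; 9 up and 2 down adjusted over the list alone; adjusted p = 0.526 with an estimated correlation). Pck1 (0.59, SE 0.32, adjusted p = 0.280) and G6pc (1.31, SE 0.47, adjusted p = 0.114), the rate-setting enzymes of glucose output, did not pass. Cholesterol biosynthesis genes fell, 9 of 24 over all genes and 18 adjusted over the list alone (median -1.88, or -0.40 with slide as a block; adjusted p = 0.467 with an estimated correlation), among them Nsdhl (-2.75), Mvd (-2.69) and Fdps (-2.36). Of the genes of fatty acid and triglyceride synthesis 6 fell, including Srebf1 (-4.06) and Elovl6 (-2.12), and 2 rose, Cidec (5.68) and Lpin1, with 2 up and 8 down adjusted over the list alone (median -0.70, or -0.58 with slide as a block, where the call was lost at adjusted p = 0.461; adjusted p = 0.492 with an estimated correlation). Fatty acid oxidation genes rose, 7 of 23 over all genes and 10 adjusted over the list alone (median 0.72, or 0.89 with slide as a block; adjusted p = 0.467 with an estimated correlation), with Acot1 at 3.13, Cyp4a10 at 2.30 and Acadl at 1.00. Of 6 adipocyte markers, Plin4 (4.51), Cidea (2.41) and Fabp4 (1.92) rose and Car3 (-3.55) and Lpl fell (median 1.64, camera adjusted p = 0.156).

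Many inflammatory genes had lower signal in treated HESKOL liver. In the list of NF-kB and cytokine genes 8 of 23 fell and 1 rose over all genes, with 13 down and 2 up adjusted over the list alone (median -1.77, or -1.65 with slide as a block; adjusted p = 0.492 with an estimated correlation). Il1b, which encodes interleukin 1 beta, fell 16.6-fold (-4.05, SE 0.40), Tnf at least 7.08-fold and Tnfaip2 7.43-fold, whereas the adhesion molecule gene Vcam1 rose 3.57-fold. Camera also called lower medians for interferon response (-0.91, or -0.29 with slide as a block; 2 of 23 down; adjusted p = 0.492 with an estimated correlation), lymphocyte markers (-1.08, or 0.20 with slide as a block; 1 of 20 down, Cd79a; adjusted p = 0.492 with an estimated correlation), macrophage markers (-0.87, or -0.17 with slide as a block; Adgre1, Lyz2 and Lyz1 down and Cd163 up; adjusted p = 0.585 with an estimated correlation) and cell cycle (-1.59, or -1.001 with slide as a block; 1 of 25 down, Tk1; adjusted p = 0.529 with an estimated correlation). Neutrophil markers had a median of -2.29 (-1.01 with slide as a block), with 12 of 13 members lower and none past the threshold, and were not called (camera adjusted p = 0.131, fry adjusted p = 0.596). Their list medians in single livers ran from -1.98 to 2.76 without and from -4.15 to -0.04 with treatment, so the groups overlapped. The unfolded protein response list was called higher (median 0.68, or 0.06 with slide as a block; 1 of 21 up, Trib3; adjusted p = 0.526 with an estimated correlation). With slide as a block the calls of the macrophage (adjusted p = 0.341), lymphocyte (adjusted p = 0.974) and unfolded protein response lists (adjusted p = 0.940, with the test's direction down) were lost.

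**Figure D3:**
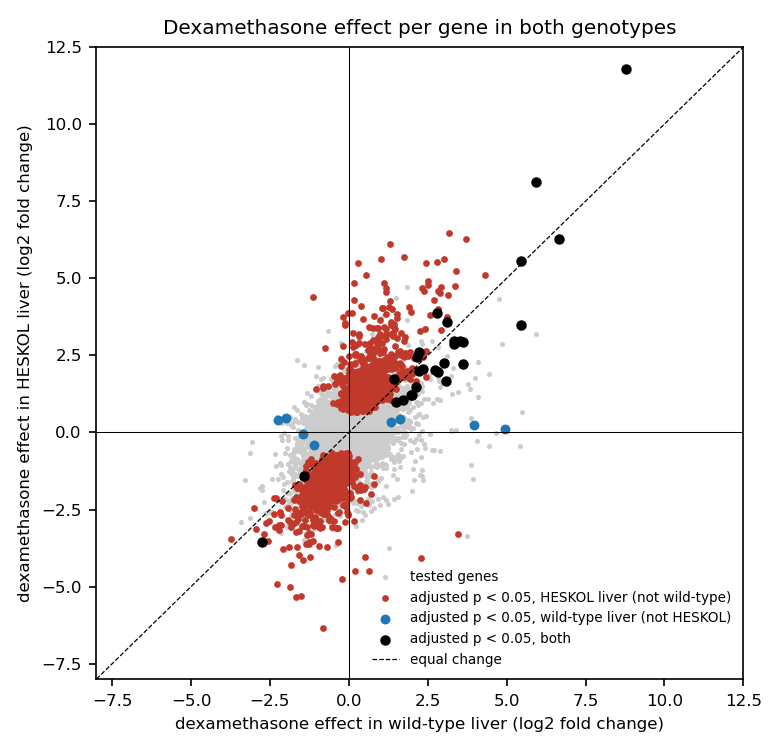
Dexamethasone effect of each of the 18728 tested genes in wild-type liver (x axis, log2 fold change) and HESKOL liver (y axis, log2 fold change). Colours mark genes past adjusted p 0.05 in either genotype, and the dashed line marks equal change; 26 genes rose and 2 fell in both.

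The dexamethasone effects of the 2 genotypes were then set side by side. Across genes their correlation was r = 0.59 (Spearman rho 0.55), with no array shared between the comparisons; genes are not independent replicates, so no p is given. This correlation ran from 0.40 to 0.67 when single arrays were left out. In both genotypes 26 genes rose, where independent lists would share 1.09, and 2 fell, where they would share 0.253, and no gene went opposite ways. Of the 1473 genes called in HESKOL liver 1363 (92.5%) had the same sign in wild-type liver, against 70.1% of all 18728 tested genes. The median change of the 1473 genes in that direction was 0.62 in wild-type liver compared with 1.54 in HESKOL liver. These genes were selected by their calls in HESKOL liver, which raises their HESKOL median, so the gap does not measure a weaker wild-type response. In single treated wild-type livers their median in that direction was 0.203, 0.651 and 0.931 for replicates 1, 2 and 3. The slides do not separate from treatment here, since in both genotypes no treated liver shared a slide with an untreated one of its genotype.

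The test of the difference between the responses called 3 genes. Phf11d changed by 3.13 in HESKOL and 0.30 in wild-type liver (difference 2.83, SE 0.30, adjusted p = 0.0193), Sesn1, a p53-regulated stress gene, by 2.76 and 0.12 (difference 2.63, SE 0.30, adjusted p = 0.0243) and Il1b by -4.05 and 0.52 (difference -4.57, SE 0.57, adjusted p = 0.0343). At an unadjusted p under 0.05 there were 1244 genes. Under the slide block none of the 3 passed, with differences of 2.55, 2.30 and -4.94. The count was 9 without wild-type dexamethasone replicate 1, 13 without replicate 2 and 6 without replicate 3. It was 0 without wild-type untreated replicate 2, without any 1 of the 3 HESKOL untreated replicates, and without HESKOL dexamethasone replicate 2 or 3. Ppargc1a (difference 2.62, SE 0.47, adjusted p = 0.183) did not pass. For Hes1 the difference was 0.02 (SE 0.61), and 0.55 without wild-type dexamethasone replicate 1.

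Without treatment, no gene separated HESKOL from wild-type liver past the threshold (limma, smallest adjusted p 0.367), with 297 genes at an unadjusted p under 0.05 where 936 are expected by chance. The 5 named genes with the smallest p were Cux2, a transcription factor of female liver (3.66 higher in HESKOL, SE 0.54, 12.7-fold; above background on 1 of 3 wild-type arrays), the cadherin gene Cdh15 (-1.48, SE 0.23), Hao2 (at least 5.58-fold higher), Drd3 (-0.95) and Cables1 (1.35). Within slide 1, which holds 1 HESKOL and 3 wild-type livers, Cux2 differed by 4.09 (SE 0.82) and Cdh15 by -1.13 (SE 0.31). The groups did not overlap in 6.36% of genes, below the 10% that chance gives. Without wild-type untreated replicate 3, 1 gene passed.

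The list of genes more active in female than in male liver was higher in untreated HESKOL livers, all from male mice. Of its 17 members 13 had positive differences (median 0.29), none passed over all genes and 4 passed adjusted over the list alone, with Slc22a26 at 3.55 (SE 1.14) and the cytochrome P450 gene Cyp2b9 at 3.21 (SE 0.83). Camera gave adjusted p = 2.2e-08 and adjusted p = 0.00571 with an estimated correlation, the only list to hold in this comparison, and the median within slide 1 was 0.37. Genes more active in male liver had negative differences in 16 of 16 members (median -0.37; -0.12 within slide 1), with Hsd3b5 at -3.00 (SE 0.98), and the camera call was lost at adjusted p = 0.488 with an estimated correlation. Macrophage markers had a median of 0.42 (0.50 within slide 1; adjusted p = 0.913 with an estimated correlation), immediate early genes of 0.40 (0.54 within slide 1; adjusted p = 0.955 with an estimated correlation) and endothelial markers of 0.22 (0.22 within slide 1; adjusted p = 0.488 with an estimated correlation). The remaining lists called by camera were NF-kB and cytokine genes (median 0.23), fatty acid oxidation (0.20), lymphocyte markers (0.24), circadian clock (-0.12) and heat shock proteins (-0.17), none with an estimated correlation (adjusted p = 0.955, 0.913, 0.955, 0.488 and 0.913 with an estimated correlation). Within slide 1 their medians were 0.29, 0.39, 0.42, 0.13 and 0.02, so those of the clock and heat shock lists changed sign, and both calls were lost (adjusted p = 0.843 and 0.916).

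After dexamethasone, HESKOL and wild-type livers differed in more genes. Cux2 was 221-fold higher in HESKOL liver (log2 difference 7.79, SE 0.54; above background on 1 of 3 wild-type arrays), and the leptin receptor gene Lepr was higher by 4.17 (SE 0.54). Trp63 (23.5-fold), Lancl3 (21.5-fold), Nipal1 (18.3-fold), Cyp4a14, a fatty acid hydroxylase gene (16.1-fold), Fibin (14.6-fold), Itga2 (13.6-fold) and Cdc42ep5 (12.8-fold) were also higher, as was Ptgfr, at least 4.85-fold. Lower in HESKOL liver were the neutrophil chemokine gene Cxcl1 (133-fold; -7.05, SE 0.90), Hcar2 (81.3-fold), Gadd45a (46.2-fold), the male-biased steroid genes Hsd3b5 (42.0-fold) and Hsd3b4 (29.1-fold), the cytokine signaling inhibitor Socs1 (39.9-fold), Rnf186 (25.2-fold), the repressor Bcl6 (15.4-fold) and Gdf15 (13.6-fold). Trp63 and Lancl3 were above background on 1 and Itga2 on 2 of the 3 wild-type arrays, and Hcar2 on 2 of the 3 HESKOL arrays. Wild-type dexamethasone replicate 1 carried part of several folds: without it the difference was -3.91 for Socs1, -3.99 for Gadd45a, -5.06 for Hcar2, -6.32 for Cxcl1, -3.70 for Rnf186 and -2.96 for Gdf15, and 3.20 for Fibin, 3.82 for Lancl3 and 2.87 for Itga2. Trp63 (4.12, adjusted p = 0.0648; 4.55 with that array), Hsd3b5 (-4.87, adjusted p = 0.0506; -5.39 with it) and Hsd3b4 (-4.35, adjusted p = 0.0726; -4.86 with it) then missed the threshold.

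These were among 130 genes higher and 84 lower (limma, adjusted p under 0.05), with 2945 at an unadjusted p under 0.05; groups did not overlap in 18.2% of genes against 10% by chance. Without wild-type dexamethasone replicate 1 the count was 459, of which 172 were shared. It was 122 without replicate 2 of that group, 85 and 99 without wild-type untreated replicates 2 and 3, 101 and 114 without HESKOL untreated replicates 1 and 2, and 94, 33 and 75 without HESKOL dexamethasone replicates 1, 2 and 3. Within slide 3, which holds 1 wild-type and 3 HESKOL livers, 3 genes passed (Cux2, Pcdh19 and Rspo4). All 214 genes had the same sign, but this was fixed in advance and is no check of the calls. In all 214 the 3 HESKOL livers already lay on one side of every wild-type liver, including the one on slide 3. The median difference of the 214 genes within slide 3 was 1.87 compared with 1.93. There Cux2 differed by 7.62 (SE 0.82), Il1b by -3.96 (SE 0.61) and Cxcl1 by -7.62 (SE 1.38). On unscaled deposited signals the split was 331 higher and 60 lower, with the median of all genes at 0.20.

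NF-kB and cytokine genes were lower in treated HESKOL than in treated wild-type liver, 5 of 23 over all genes and 16 lower and 1 higher adjusted over the list alone (median -1.71; -1.62 within slide 3; adjusted p = 0.433 with an estimated correlation). Examples were Cxcl1, Il1b (-3.68, SE 0.40), Tnfaip2 (-1.71, SE 0.32; adjusted p = 0.0511 without wild-type dexamethasone replicate 1) and Irf1 (-1.90, SE 0.39). Fatty acid oxidation genes were higher, 3 of 23 over all genes and 8 adjusted over the list alone (median 0.86; 0.82 within slide 3; adjusted p = 0.433 with an estimated correlation), with Cyp4a14, Cpt1a (1.31) and Acadl (1.03) past the threshold. Amino acid catabolism had a median of 0.84 (0.73 within slide 3) and gluconeogenesis of 0.53 (0.66 within slide 3), with 6 and 5 members higher adjusted over the list alone and adjusted p = 0.502 and 0.668 with an estimated correlation, and within slide 3 the call of gluconeogenesis was lost (adjusted p = 0.111); Ppargc1a was 2.98 higher (SE 0.33). Cholesterol biosynthesis had a median of -0.92 (0.17 within slide 3, so the sign changed and the call was lost at adjusted p = 0.376), with no member past the threshold over all genes, 7 lower adjusted over the list alone and adjusted p = 0.502 with an estimated correlation. Its median was -0.19 without wild-type dexamethasone replicate 1. Female-biased genes stood at 1.01 (0.66 within slide 3; 1 of 17 up, Cux2; adjusted p = 0.140 with an estimated correlation) and male-biased genes at -0.54 (-0.53 within slide 3; 1 of 16 down, Hsd3b5; adjusted p = 0.502 with an estimated correlation).

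Camera called 9 further lists lower in treated HESKOL liver, none of them with an estimated correlation. Medians were -1.10 for immediate early genes (-0.63 within slide 3), -0.52 for the unfolded protein response (-0.83), -0.56 for heat shock proteins (-0.95), -0.71 for fatty acid and triglyceride synthesis (-0.23) and -0.18 for the circadian clock (-0.16), each at adjusted p = 0.502 with an estimated correlation. They were -0.45 for interferon response (0.06 within slide 3) and -0.20 for acute phase proteins (-0.50), at adjusted p = 0.646 with an estimated correlation, and -0.48 for cholangiocyte markers (-0.11 within slide 3), at adjusted p = 0.557 with an estimated correlation. The last list was that of neutrophil markers, with a median of -1.74 (-0.48 within slide 3; adjusted p = 0.771 with an estimated correlation) and no member past the threshold. Within slide 3 the calls of interferon response (adjusted p = 0.147), fatty acid and triglyceride synthesis (adjusted p = 0.260), cholangiocyte markers (adjusted p = 0.932) and neutrophil markers (adjusted p = 0.631) were lost. Without wild-type dexamethasone replicate 1 the camera calls of interferon response (median 0.20), neutrophil markers (-0.96), cholangiocyte markers (-0.42), gluconeogenesis (0.30) and fatty acid and triglyceride synthesis (-0.20) were lost, and the medians were -0.38 for immediate early genes and -0.82 for the unfolded protein response. Of the clock genes Bhlhe40 was 7.21-fold lower (-2.85, SE 0.36).

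Camera called the other lists in none of these comparisons. Fry called 1 of them once, the Notch list with dexamethasone in HESKOL liver. Between treated HESKOL and treated wild-type liver their medians were -0.03 for the 19 Notch pathway and Hes/Hey genes, 0.17 for bile acid synthesis and transport, -0.18 for xenobiotic metabolism, 0.07 for growth hormone and STAT5 targets, 0.23 for oxidative phosphorylation, 0.06 for stellate cell markers, -0.20 for erythroid markers and -0.16 for exocrine pancreas markers. Camera's direction was down for the growth hormone and stellate cell lists despite their positive medians. Glucocorticoid receptor targets, called with dexamethasone in both genotypes, were not called between the treated genotypes (median 0.30, camera adjusted p = 0.305). In HESKOL liver dexamethasone lowered 3 Notch list members (Heyl -2.30, Hes6 -2.09 and Hey1 -1.46) and raised Notch4 (1.53), with a list median of -0.47 (-0.21 with slide as a block; 12 of 19 members lower; camera adjusted p = 0.131, or 0.467 with an estimated correlation, and fry adjusted p = 0.0285). Besides it, fry but not camera called female-biased genes (median 0.46, camera adjusted p = 0.0584, fry adjusted p = 0.0285) and adipocyte markers (fry adjusted p = 0.0368) with dexamethasone in HESKOL liver. Cyp1a2 (-2.16) and Cyp2c55 (-2.28) of the xenobiotic list were lower in treated HESKOL than in treated wild-type liver, as was the bile salt export pump gene Abcb11 (-1.26).

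**Figure D4:**
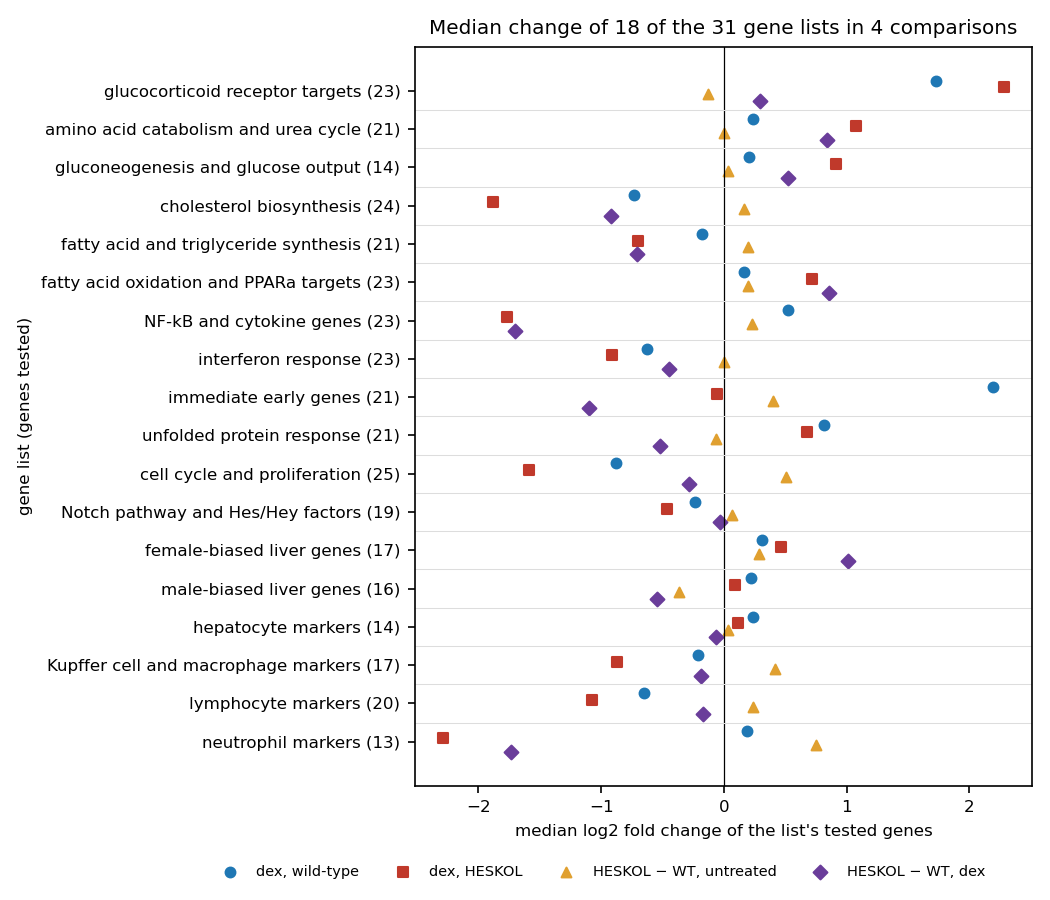
Median log2 fold change (x axis) of the tested genes of 18 gene lists (y axis, number of genes in parentheses) in 4 comparisons, shown by colour and shape. Glucocorticoid receptor targets had positive medians with dexamethasone in wild-type (1.73) and HESKOL liver (2.28), and NF-kB and cytokine genes were at 0.52 and -1.77. Without wild-type dexamethasone replicate 1 the wild-type median of the NF-kB list was 0.08 and its camera call was lost.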

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

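The counts over other splits of the samples were planned. The tests of wild-type dexamethasone replicate 1, of the slides, of the direction of the calls, of the immune lists and of the sex of the mice were chosen only after the results were seen.

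The results named here differed between the genotypes in the test of the difference between their dexamethasone responses. The difference, HESKOL minus wild-type, was 2.83 for Phf11d, 2.63 for Sesn1 and -4.57 for Il1b. As list medians it was -2.17 for NF-kB and cytokine genes, -1.40 for immediate early genes, 0.90 for amino acid catabolism, -1.27 for cholesterol biosynthesis, 0.64 for fatty acid oxidation, -0.57 for macrophage markers and -0.78 for cholangiocyte markers. It was -0.41 for interferon response, -2.41 for neutrophil markers, -0.60 for fatty acid and triglyceride synthesis, 0.64 for gluconeogenesis and -0.37 for the unfolded protein response. It was -0.32 for acute phase proteins, -0.49 for lymphocyte markers and -0.67 for cell cycle genes. These 15 lists were called by camera with its preset correlation and none with an estimated correlation. Without wild-type dexamethasone replicate 1 the calls of the macrophage (median -0.16), cholangiocyte, interferon (median 0.06), neutrophil (median -1.65), fatty acid synthesis (median -0.40), gluconeogenesis, lymphocyte (median 0.02) and cell cycle lists were lost, and the medians of immediate early genes, cholesterol genes and the unfolded protein response were -0.70, -0.55 and -0.61. With slide as a block the calls of the cholesterol (median -0.25, adjusted p = 0.255), fatty acid oxidation (0.35, adjusted p = 0.405), gluconeogenesis (0.68, adjusted p = 0.074), fatty acid synthesis (-0.51, adjusted p = 0.081), acute phase (-0.09, adjusted p = 0.102), lymphocyte (0.06, adjusted p = 0.990), cell cycle (0.45, adjusted p = 0.918), cholangiocyte (0.0168, adjusted p = 0.990) and neutrophil lists (1.46, adjusted p = 0.230) were lost. The blocked medians of the 6 lists still called were -2.78 for NF-kB and cytokine genes, -1.09 for immediate early genes, 0.62 for amino acid catabolism, -0.53 for macrophage markers, -0.28 for interferon response and -0.96 for the unfolded protein response. Of 100 splits of the samples 11 gave at least 3 genes, so chance is not excluded for that count, and the highest other split gave 80 genes. That split kept the treated livers apart by genotype and mixed the untreated ones, so the difference between the treated genotypes enters it. As many as 15 lists were called in 16 of the 100 splits, with 20 in the highest other split, so chance is not excluded for the lists either.

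For the other comparisons, 3 against 3 arrays make 10 splits, too few for a share under 0.05. The real split gave 36 genes for dexamethasone in wild-type liver and 1473 in HESKOL liver, with 0 in the highest other split of each, and was the 1 split of 10 with as many. After dexamethasone the genotypes gave 214 genes, 1 split of 10, against 0 in the highest other. Without treatment the real value was 0, as in all 10 splits (limma, 297 genes at an unadjusted p under 0.05). Lists called in the real and the highest other split numbered 13 and 15 for dexamethasone in wild-type liver, 12 and 16 in HESKOL liver, 10 and 19 between the untreated genotypes, and 16 and 14 between the treated ones. As many lists as in the real split came from 3, 7, 6 and 1 of the 10 splits.

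Dexamethasone called more genes in HESKOL than in wild-type liver, 1473 against 36. Wild-type dexamethasone replicate 1 may account for part of this: with that array and 1 HESKOL dexamethasone array left out together, the ratio of the counts was 2.17, 1.84 and 1.56 (lowest 1.563). The spread was estimated over all groups, so a gene's SE is the same in both comparisons (0.43 for Hes1 in each). That array therefore widens the SE of both, whereas it shifts the treated mean in wild-type liver alone. Its effects through the SE and through that mean were not separated. Under a slide block 0 genes were called in HESKOL liver (1201 at an unadjusted p under 0.05), as in wild-type liver (610). The median change of the 1473 HESKOL genes, in the direction of their calls, fell from 1.54 to 1.01. Their median SE rose from 0.33 to 0.58 and 6 residual degrees of freedom were left. Wild-type dexamethasone replicate 1, on slide 2, also enters these blocked changes directly. These parts were not separated, so the slides and the treatment cannot be told apart for the count. Slide 3 as the whole source of the direction of the HESKOL calls is argued against by wild-type dexamethasone replicates 1 and 2, on slide 2. They changed in that direction by medians of 0.203 and 0.651, above the highest untreated wild-type array at 0.080. Each untreated wild-type array was measured from a mean that includes it, which lowers that bar, so the margin of replicate 1 is less certain. Untreated HESKOL arrays were not part of that bar. A difference between genotypes in the response stays open; of 18728 genes and 31 lists tested for it, the 3 genes and 15 lists above passed.

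Wild-type dexamethasone replicate 1 stood apart from its group. Its median of glucocorticoid receptor targets was 1.58, above the highest untreated array at 0.335, and 18 of the 23 members exceeded all 6 untreated arrays, against 21 and 19 in replicates 2 and 3. Since Fkbp5 and Tsc22d3 did not exceed them, a smaller or absent dose in that mouse cannot be told apart from another stress on the animal or tissue. More immune cells in the sample stay open. The macrophage (0.559), lymphocyte (0.367) and neutrophil (1.71) lists lay above both other treated wild-type livers in 3 of 3 cases. In 0 of 3 they lay above the highest of all 6 untreated arrays (0.578, 0.417 and 3.28), of which the first 2 were HESKOL arrays. Above the highest untreated wild-type array lay 2 of 3, the macrophage (against 0.142) and lymphocyte lists (against 0.216), and the neutrophil list lay below it (3.28). A weaker fall of these lists therefore cannot be told apart from added cells. No biological explanation was tested.

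Female-biased genes were higher in HESKOL liver. Female mice under the HESKOL label are argued against by 4 Y-linked genes, each well above background on all 6 HESKOL arrays. The slides as the source are argued against by the median differences within slide 1 (0.3695) and slide 3 (0.66), where every HESKOL array exceeded every wild-type array of its slide. For the male-biased genes the slides and the genotype cannot be told apart: the HESKOL array of slide 1, at -0.12, lay within the wild-type range of -0.366 to 0.327. The genotype is an open explanation of the female-biased pattern, resting on 1 HESKOL array in slide 1 and 1 wild-type array in slide 3, and an effect of the labels' gene on sex-biased liver expression is a hypothesis.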

How the results depend on the processing

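Array weights, array brightness as a covariate and the fits without 2 treated arrays were chosen after seeing the data; the other alternatives were planned. Of 4114 recomputations of the 138 called values of named genes, 3148 kept direction and threshold, 966 kept the direction alone and 0 reversed. For the fits with arrays left out this 0 was largely fixed in advance. Groups that do not overlap cannot change order when arrays are removed. They did not overlap in 36 of 36 genes called in wild-type liver, 1472 of 1473 in HESKOL liver and 214 of 214 between treated genotypes. Of 1980 recomputations of the 66 called lists, 1609 kept direction and threshold, 359 kept the direction alone and 12 reversed. The counts for dexamethasone in wild-type liver, in HESKOL liver, between genotypes after it and for the difference in response were 36, 1473, 214 and 3. Without a filter the first 3 were 22, 945 and 106. The slide block gave 0, 0, 3 and 0 with 6 residual degrees of freedom; the SE rose, and the median changes of the called genes fell from 2.74 to 2.30 in wild-type and from 1.54 to 1.01 in HESKOL liver. Slide as a random block gave 2395 genes in HESKOL liver and 7 for the difference. In that fit the estimated correlation between arrays of the same slide, beyond their group means, was -0.06. Slides and groups largely coincide, so this value is a limited measure of slide effects. Fits on the groups compared gave 0 in wild-type liver and 8 between treated genotypes, with fewer residual degrees of freedom. An adjusted p under 0.01 gave 10, 263, 27 and 0. Array weights gave 1930, 4716, 1001 and 140, and 13 between untreated genotypes, and the brightness covariate 231, 2335, 1226 and 28. Normexp with quantile normalization gave 344 between treated genotypes and 9 for the difference, deposited values 391 and 0, and the mean of the probes of a gene 1 for the difference. Without wild-type dexamethasone replicate 1 and HESKOL dexamethasone replicate 1, 2 or 3, wild-type liver gave 953, 926 and 1107 and the difference 5, 0 and 0, and without replicate 2 the treated genotypes gave 83. Leaving out each array gave 11 to 1110, 364 to 2801, 33 to 459 and 0 to 13, and 0 to 1 between untreated genotypes; where this left 2 arrays in a group, the spread was pooled over all groups. The causes of these shifts were not tested.

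With the replicate number as a block the counts were 29, 1490, 125 and 2, and 0 between untreated genotypes. The numbers do not pair the mice: 18 pairs with equal numbers correlated at -0.40 to 0.62, and 4 of 12 arrays correlated best with their own number. The correlation of dexamethasone effects, 0.59, was 0.47 with the brightness covariate, 0.68 without both replicate 1 of wild-type and replicate 2 of HESKOL dexamethasone, and 0.40 to 0.67 with single arrays left out. Of the 66 list calls 2 held with an estimated correlation and 11 with fry; fry passed 14 lists in all.

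These 12 list tests reversed direction, 10 of them with the sign of the median, and the cause was not tested. Under the slide block the medians were 0.13 and 0.20 for lymphocyte markers with dexamethasone in wild-type and HESKOL liver, 0.057 for the unfolded protein response in HESKOL liver (reversed by the test's direction alone), and 0.45 for cell cycle, 0.0168 for cholangiocyte and 1.46 for neutrophil markers in the difference. Without replicate 1 of wild-type and replicate 3 of HESKOL dexamethasone, interferon response was at 0.37 and neutrophil markers at 0.10 between treated genotypes, and interferon response at 0.22 and lymphocyte markers at 0.40 in the difference. With single arrays left out, the cell cycle list in wild-type liver ran from -1.36 to 0.21, and fatty acid oxidation between untreated genotypes from 0.00202 to 0.26, reversed by the test's direction alone. In 19 more recomputations the median changed sign and the test's direction did not. Under the slide block these were the clock (0.13) and heat shock lists (0.02) between untreated genotypes, interferon response (0.06) and cholesterol biosynthesis (0.17) between treated ones and lymphocyte markers (0.06) in the difference. With replicate 1 of wild-type dexamethasone left out, alone or with a HESKOL dexamethasone array, they were interferon response between treated genotypes (0.20 and 0.09) and interferon (0.06 and 0.03), lymphocyte (0.02 and 0.02) and macrophage lists (0.06) in the difference. The others were interferon response between treated genotypes with array weights (0.11) and, in wild-type liver, amino acid catabolism on deposited values (-0.089) and with the brightness covariate (-0.0006) and hepatocyte markers after quantile normalization without and with normexp (-0.012 and -0.010), on deposited values (-0.091) and with the brightness covariate (-0.093). Signal over background limits what can be measured: 62.2% to 72.3% of spots per array were well above it, and dim probes limit some folds to bounds, such as that of Fam107a in HESKOL liver, while in wild-type liver its fold rests on untreated arrays of which 1 of 3 was above background.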

Other observations

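The values here were chosen after the data were seen, and no explanation of them was tested. Within groups, list medians of single arrays, relative to the mean of untreated wild-type liver, were far apart for some cell types. The neutrophil list stood at 3.28 in wild-type untreated replicate 1 and at -1.37 and -1.70 in replicates 2 and 3, and at -1.98, 2.76 and 1.58 in the HESKOL untreated livers. The cell cycle list stood at 1.85 in wild-type untreated replicate 1 and at -0.91 in replicates 2 and 3. In wild-type dexamethasone replicate 1 the cholesterol biosynthesis list stood at 0.51 and the interferon list at 0.23, while in replicates 2 and 3 they stood at -1.19 and -1.40 and at -1.20 and -0.85. In the 3 treated HESKOL livers the cholesterol list lay between -1.80 and -1.45.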
